A study of Mus musculus with 8 samples.

How the data were processed

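Droplet-based single-cell RNA sequencing (10x Genomics 3' chemistry, version 3, per the labels' protocols) measured CD8+ cells from subcutaneous MC38 tumours of C57BL/6 mice at day 12. There were 2 aged libraries (mice of 20 to 22 months) and 2 young libraries (3 to 4 months). Mice within a library were told apart by hashtag antibodies against CD45 and MHC class I, with 4, 3, 4 and 4 hashtags in aged replicates 1 and 2 and young replicates 1 and 2. The deposited matrices hold raw UMI counts for 32285 genes and for the hashtags, made by the authors with Cell Ranger 4.0.0 against mm10, per the submitters' processing notes, which also name Seurat 3.2.2 and R 4.0.3. The matrices hold 15507, 24131, 18086 and 16040 barcodes in that order, with 41590105, 60466831, 58628797 and 65057393 hashtag UMIs. The smallest number of UMIs per barcode was 500 in 3 libraries and 1350 in aged replicate 2.

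Barcodes with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs were kept. Hashtag counts were normalised by centred log ratio and assigned with HTODemux of Seurat 5.3.0 at a quantile of 0.99. Cells assigned to 1 mouse made up 64.9%, 38.0%, 70.7% and 79.5% of the cells kept in the 4 libraries. A Gaussian mixture on the same hashtag counts gave the same mouse for 92.5%, 40.6%, 90.5% and 93.5% of them, so the assignment of aged replicate 2 is less certain. Scrublet called 1 doublet in that library and did not separate doublets there.

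Counts were scaled to 10000 per cell and log-transformed. Cells were clustered with scanpy 1.11.5 on 2000 variable genes, 30 principal components and 15 neighbours with the Leiden method at a resolution of 0.6 (igraph 0.11.9). T cell receptor, immunoglobulin, ribosomal, mitochondrial and sex-specific genes were left out of the variable genes. Libraries were not integrated, so differences between libraries could also enter the clusters. A first round over all assigned cells gave 16 clusters. Clusters with Cd3 and with Cd8 UMIs in over 50% of cells and fewer than 3 markers of another cell type among the 10 leading genes were kept. They were clustered again into 10 clusters, of which 8 passed the same rule. This second round was chosen after the data were seen. Leading genes were ranked by fold change of cluster over other cells with a pseudocount of 10 CPM among genes detected in at least 10% of the cluster, and a name was given only from marker lists fixed beforehand. First-round cluster 3 (Acp5, Mmp9; 4436 cells, of which 3477 were from aged replicate 2), first-round cluster 5 (H2-Aa, Cd74; 3218 cells), and second-round clusters 6 (Klra1, Ncr1; 258 cells) and 8 (H2-Aa, Lyz2; 161 cells) held T cell transcripts but were left out under the rule. The CD8 T-like cells numbered 2184, 963, 3710 and 3805 in the 4 libraries, with median UMIs of 1894, 2928, 2190 and 2661 per cell.

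Counts were summed over each mouse's CD8 T-like cells (at least 100 cells per mouse, and at least 30 within a cluster). Ages were compared with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) after filterByExpr and TMM scaling, two-sided, with Benjamini-Hochberg adjustment at 0.05. The standard error printed is the absolute log2 fold change divided by the square root of the test's F statistic. Shares of clusters were compared by two-sided exact permutation over all 6435 splits of the 15 mice, whose smallest p is 0.0002, with Benjamini-Hochberg adjustment over clusters. Because genes that differ between ages helped to form the clusters, the shares were also computed from a clustering without them, and 63.7% of cells stayed in the corresponding cluster. Gene lists fixed beforehand were tested where at least 3 members were measured, with camera of limma 3.58.1 at a preset correlation of 0.01, camera with an estimated correlation, and fry. The neutrophil and erythroid lists had too few measured members to be tested. The age difference between clusters was tested with limma on the within-mouse difference. Trbv evenness used UMIs thinned in 200 draws, and the minimum of 25 UMIs was chosen after the totals were seen.

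Genes named were fixed by rule before the data were examined. Over all CD8 T-like cells, they were the 10 genes with the largest change in each direction (5 within a cluster) among genes past the threshold, of at least 20 CPM in 1 age and changed the same way in all libraries (in summed counts). A list of 27 genes was added whatever its result, and up to 4 members with the smallest p for each gene list. Some of the genes that the rule names are not reported here. Receptor, ribosomal, haemoglobin, sex-linked and predicted genes were excluded from the ranking. Leading genes that describe clusters, the genes of the difference between clusters and those of macrophage-like and large cells were named after the data were seen. Gene positions are those of GENCODE vM21 (mm10), which held 32235 of the 32285 gene identifiers.

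The alternatives tried for genes were DESeq2 1.42.0, size factors in place of TMM, no filter on low counts and a prior count of 0.5 in place of 2. Others were looser cell limits (200 genes, 500 UMIs, 20% mitochondrial), Scrublet calls left out, equal cell numbers, all assigned cells, a gate on Cd3 and Cd8 UMIs, and the Gaussian mixture. Further ones were other resolutions (0.3 and 1.0), clusters defined in young cells alone, sums per library, replicate or library as a block, and leaving out each library and each mouse. Those added after the data were seen were genes at or above their level in other cells, pooling aged replicate 2, cells of no hashtag, crossed replicate numbers as a block, and comparisons in macrophage-like and in large cells. Each test was tested on simulated data with 200 changed genes. The simulated mice carried no differences between libraries, so the rates that follow leave out false calls from library differences. The test over all CD8 T-like cells recovered 89% of genes changed by 1 log2 unit and 98% by 2, with 3.11% false calls. In cluster 1 it recovered 87% and 92% with 8.67% false calls, above the 5% aimed at, and in cluster 2 86% and 80% with 4.05%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were also used.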

Results

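CD8+ cells that had infiltrated subcutaneous MC38 tumours, a transplantable colon adenocarcinoma line of C57BL/6 origin, were profiled by droplet-based single-cell RNA sequencing at day 12 after implantation. The design asks how tumour-infiltrating CD8 T cells differ between young adult mice (3 to 4 months) and aged mice (20 to 22 months). Each age had 2 libraries, and each library pooled 3 or 4 mice whose cells carried a mouse-specific hashtag, an antibody-linked barcode. The libraries held 163602241 and 150733543 gene UMIs (unique molecular identifiers) for aged replicates 1 and 2, and 189228463 and 211046020 for young replicates 1 and 2. Of 73764 barcodes, 62020 passed the cell filter and 37637 were assigned to 1 mouse. Although the submitters describe CD8+ cells, the assigned cells also included macrophage-like cells led by Lyz2, Arg1 and Apoe, and large cells in 3 clusters, of which 1 was led by the collagen gene Col3a1 and 1 by the mitotic gene Cenpf. The 10662 cells in CD8 T-like clusters, 3147 from 7 aged and 7515 from 8 young mice, were compared between ages. They numbered 164 to 1500 per mouse, with 428769 to 4140547 UMIs per mouse. CD8 T-like cells made up 20.8% ± 15.2 (SD, n = 7) of the assigned cells in aged mice and 33.8% ± 10.7 (SD, n = 8) in young mice, a difference that did not pass a two-sided exact permutation test (p = 0.0774).

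The CD8 T-like cells formed 8 clusters, which are identified by number. Cluster 1 was interferon-stimulated-like and led by Ifit3, Ifit1, Rsad2 and Isg15, antiviral genes induced by type I interferon. Cluster 2 was naive or central memory-like, with Klf2 and S1pr1, genes of quiescence and tissue egress, and Tcf7 among its leading genes. Cluster 3 was proliferating-like (Pclaf, Birc5, Mki67), and cluster 4 was granzyme K memory-like (Gzmk, Eomes) and also led by Tox and Maf. The others were left unnamed. Cluster 0 was led by Gpm6b, Slc17a6, Igfbp7 and Lag3 (an inhibitory receptor), cluster 5 by Il2, Ccl4 and Xcl1, cluster 7 by Gzmd, Gzme and Gzmf, and cluster 9 by the heat shock genes Hspa1a and Hspa1b. Clusters 0, 5 and 7 had 1, 2 and 2 markers of terminal exhaustion among their 10 leading genes, and cluster 4 was named on 2 granzyme K memory markers, so its name is weakly supported.

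Aged tumours held a larger share of the naive or central memory-like cluster 2 and a smaller share of the Lag3-expressing cluster 0. Cells were first compared after clustering without the 1567 genes that differed between ages, because leading genes of clusters 2 and 4 were among them. In that clustering, the cluster holding most cells of cluster 2 made up 63.8% ± 17.2 (SD, n = 7) of CD8 T-like cells in aged and 26.1% ± 10.2 (SD, n = 8) in young mice (two-sided exact permutation test, Benjamini-Hochberg adjusted p = 0.0033). It had also taken in 720 of the 859 granzyme K memory-like cells of cluster 4 and 1383 of the 2543 cells of cluster 1. Cluster 4 did not form without these genes. The counterpart of cluster 0 made up 7.92% ± 10.4 (SD, n = 7) in aged and 32.8% ± 13.6 (SD, n = 8) in young mice (exact permutation test, adjusted p = 0.0044). The counterpart of cluster 5 made up 4.63% ± 2.04 (SD, n = 7) and 13.1% ± 7.35 (SD, n = 8), respectively (exact permutation test, adjusted p = 0.0033). Of its 1115 cells, 463 came from cluster 5, 422 from cluster 0 and 119 from cluster 3, so its share is not that of cluster 5 alone.

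In the clustering that used all genes, the granzyme K memory-like cluster 4 made up 25.4% ± 13.6 (SD, n = 7) of CD8 T-like cells in aged mice and 0.736% ± 0.448 (SD, n = 8) in young mice (exact permutation test, adjusted p = 0.0006). The naive or central memory-like cluster 2 made up 37.8% ± 15.7 (SD, n = 7) and 9.29% ± 4.51 (SD, n = 8), with the same adjusted p = 0.0006 in the exact test. Eomes, Tox, Gzmk and Maf, which led cluster 4, differed between ages themselves, so the share of cluster 4 partly restates their change. Cluster 4 also had no counterpart among clusters defined in young cells alone or at the lower resolution. All 7 aged mice lay above all 8 young mice in both clusters, which is the most extreme of the 6435 splits of the mice. Cluster 0 made up 8.19% ± 12.6 (SD, n = 7) in aged and 44.8% ± 16 (SD, n = 8) in young mice (exact adjusted p = 0.0025). Aged replicate 2 mouse 3 held 36.0% in cluster 0, while the other 6 aged mice lay below all young mice. Proliferating-like cells (cluster 3) made up 6.18% ± 2.89 (SD, n = 7) and 11.2% ± 2.97 (SD, n = 8; exact adjusted p = 0.0094). Cluster 5 made up 1.33% ± 0.934 (SD, n = 7) and 7.21% ± 6.06 (SD, n = 8; exact adjusted p = 0.0034). Interferon-stimulated-like cells (cluster 1) made up 18.6% ± 5.36 (SD, n = 7) and 24.0% ± 15.6 (SD, n = 8; exact adjusted p = 0.456). Cluster 7 made up 1.97% and 2.46% (exact adjusted p = 0.811), and cluster 9 made up 0.524% and 0.313% (exact adjusted p = 0.456).

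**Figure D1:**
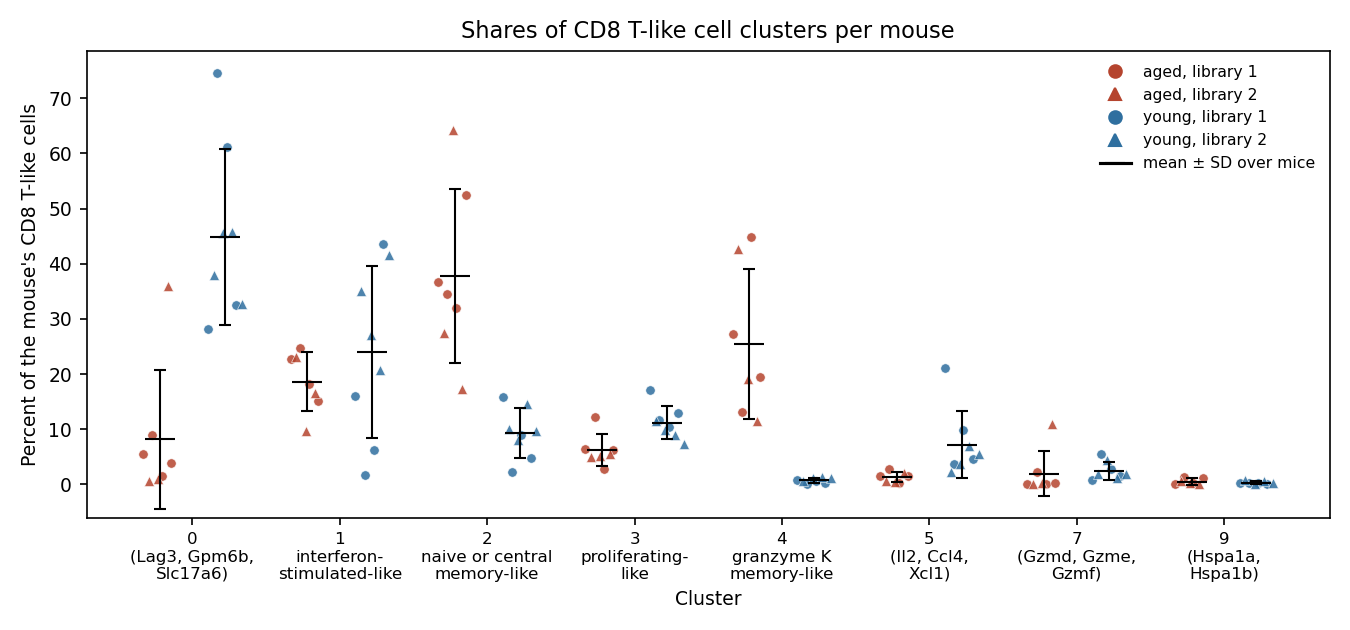
Percent of each mouse's CD8 T-like cells (vertical axis) in each cluster of the clustering with all genes (horizontal axis), for aged (red) and young (blue) mice of library replicate 1 (circles) and 2 (triangles). Bars show mean ± SD over 7 aged and 8 young mice; all 7 aged mice lie above all 8 young mice in clusters 2 and 4.

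The shares of clusters 0, 2 and 4 lay on the same side in both libraries of an age. Cluster 0 averaged 4.94% and 12.5% of CD8 T-like cells in aged replicates 1 and 2, and 49.1% and 40.5% in young replicates 1 and 2. Cluster 2 averaged 38.9% and 36.3% in the aged libraries and 7.96% and 10.6% in the young libraries, and cluster 4 averaged 26.2%, 24.4%, 0.413% and 1.06%. Each library held mice of 1 age, so library and age cannot be told apart, and an exact test over 2 libraries against 2 cannot go below p = 0.333. Several share calls did not pass with fewer mice, although differences stayed in the same direction. Cluster 0 did not pass without aged replicate 1 (-32.3 points, exact adjusted p = 0.0727) and cluster 3 without aged replicate 2 (0.107) or young replicate 1 (0.113). Cluster 5 did not pass without aged replicate 1 (-6.14 points, exact adjusted p = 0.184) or 2 (-5.69 points, 0.107). Cluster 3 also lost its call when age-dependent genes were left out of the clustering (exact adjusted p = 0.12). The interferon-stimulated-like cluster 1 turned to a 27.8 point excess in aged mice (exact adjusted p = 0.0117) when clusters were defined in young cells alone. Cluster 4 had no counterpart in that setting, so its cells took other labels. The excess of cluster 2 was 16.8 points there, against 28.5 in the main clustering. The 27.8 points may therefore include cells of clusters 4 and 2, and do not show that interferon-stimulated-like cells were more frequent.

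Over all CD8 T-like cells, aged mice expressed more of the transcription factors Eomes, Maf and Tox and of the granzyme genes Gzmk and Gzmm. Eomes, a T-box factor of memory and cytotoxic lymphocytes, averaged 111 ± 46.7 CPM (SD, n = 7) in aged and 20.5 ± 4.69 CPM (SD, n = 8) in young mice (log2 fold change 2.43, SE 0.23, adjusted p = 1.57e-06). Among genes averaging at least 20 CPM, T cell receptor genes and predicted genes aside, the largest increase was that of Kcnj8, a pore subunit of ATP-sensitive potassium channels, at 34.9 ± 22.8 CPM (SD, n = 7) against 2.27 ± 1.11 CPM (SD, n = 8; log2 fold change 3.98, SE 0.37, adjusted p = 1.57e-06). Fcgrt, the neonatal Fc receptor, rose by 3.65 on the log2 scale (SE 0.35, adjusted p = 1.84e-06), and Gzmm, which encodes granzyme M, by 3.45 (SE 0.49, adjusted p = 0.000167). Gzmk averaged 220 ± 119 CPM (SD, n = 7) and 67.4 ± 35 CPM (SD, n = 8; log2 fold change 1.64, SE 0.32, adjusted p = 0.00189). Tox, a regulator of T cell exhaustion, averaged 112 ± 66.1 CPM (SD, n = 7) and 49.4 ± 10.3 CPM (SD, n = 8; log2 fold change 1.19, SE 0.25, adjusted p = 0.00313). The other genes with the largest increases were Treml2 (2.97), G0s2 (2.85, also a marker of neutrophils), Fcgr2b (2.78), Tmem37 (2.75), Maf (2.61), Pde2a (2.5) and Klra7 (2.45). Fcgr2b and Tmem37 were higher in other cells of the tumours than in the CD8 T-like cells: Fcgr2b reached 141 CPM there in aged mice, against 26.2 CPM in their CD8 T-like cells.

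Tcf7, a factor of memory and stem-like T cells, rose by 0.86 (SE 0.22, adjusted p = 0.0117). Il7r, the interleukin-7 receptor, rose by 0.63 (SE 0.13, adjusted p = 0.00359), and the chemokine Ccl5 by 0.89 (SE 0.29, adjusted p = 0.039). Ccl5 was lower in aged replicate 2 (4924 CPM) than in young replicate 2 (5343 CPM), and its call was lost without 9 of the 15 mice in turn. By the same rule as above, the largest decreases were those of the inflammatory chemokines Ccl3 and Ccl4, with log2 fold changes of -2.35 (SE 0.62, adjusted p = 0.0149) and -2.19 (SE 0.51, adjusted p = 0.00688). Ifng, the gene of interferon gamma, averaged 285 ± 420 CPM (SD, n = 7) in aged and 1147 ± 458 CPM (SD, n = 8) in young mice (log2 fold change -1.97, SE 0.58, adjusted p = 0.0256). The other genes with the largest decreases were Slc17a6 (-2.13), Zbtb32 (-2.04), Irf4 (-1.95), Rgs16 (-1.87), Tg (-1.85), Bdh2 (-1.79) and Egr3 (-1.76). Irf4 and Egr3 are induced by T cell receptor signals. Havcr2 (TIM-3, an inhibitory receptor) averaged 41.7 ± 47.8 CPM (SD, n = 7) and 121 ± 37.6 CPM (SD, n = 8; log2 fold change -1.44, SE 0.40, adjusted p = 0.0185). Tnfrsf9 (4-1BB) had a log2 fold change of -1.38 (SE 0.38, adjusted p = 0.0182), and the killing genes Prf1 and Gzmb had -1.24 (SE 0.36, adjusted p = 0.023) and -1.05 (SE 0.30, adjusted p = 0.0207). Pdcd1 (PD-1) fell by 0.77 (SE 0.26, adjusted p = 0.048), Cxcr6 by 0.57 (SE 0.15, adjusted p = 0.0125) and Slamf6 by 0.51 (SE 0.16, adjusted p = 0.039). The call of Pdcd1 was lost without 13 of the 15 mice in turn, and that of Slamf6 without 9. Lag3 (-1.28, adjusted p = 0.0622), Gzma (-0.92, 0.0971), Mki67 (-0.43, 0.085), Cxcr3 (0.75, 0.0619), Tnf (-0.76, 0.122), Itgae (-1.14, 0.195), Klrg1 (0.81, 0.207), Entpd1 (0.18, 0.471), Tbx21 (-0.13, 0.546) and Cd28 (-0.36, 0.136) did not pass the test. Tigit and Cdkn2a had too few counts to be tested.

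**Figure D2:**
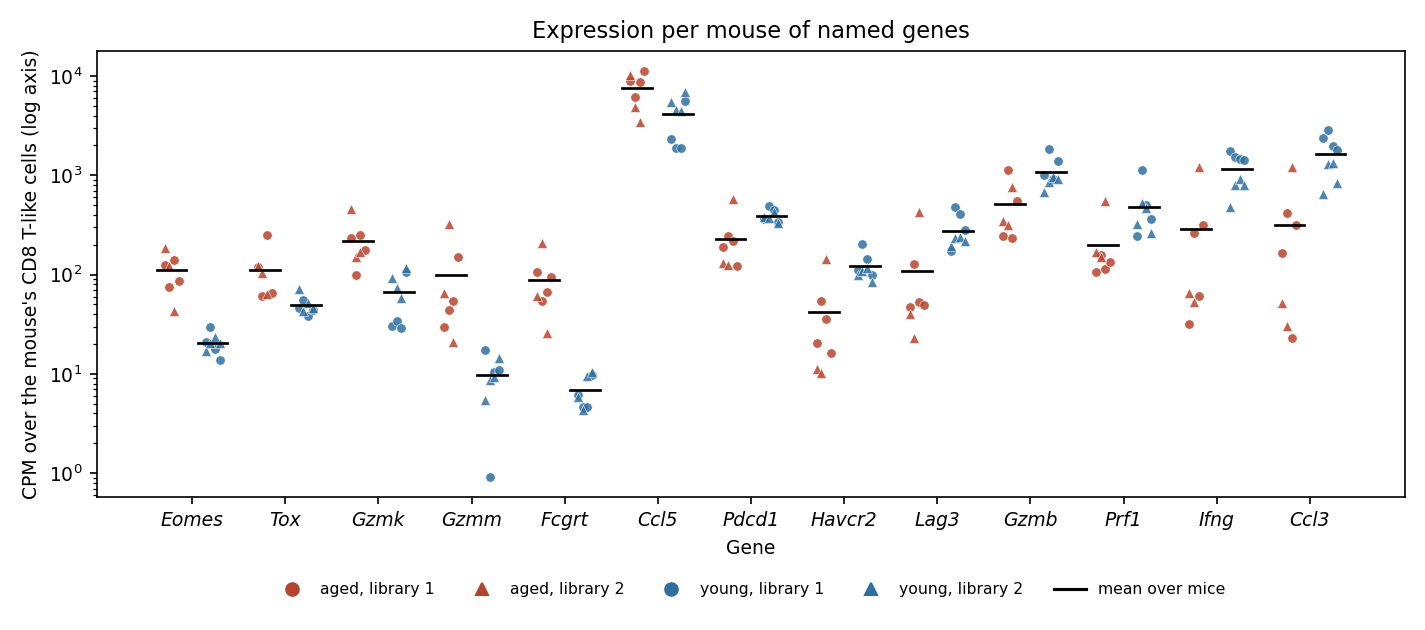
CPM summed over each mouse's CD8 T-like cells (vertical log axis) for 13 named genes (horizontal axis), in aged (red) and young (blue) mice of library replicate 1 (circles) and 2 (triangles), with horizontal lines at the means. Aged means of Eomes, Tox, Gzmk, Gzmm, Fcgrt and Ccl5 lie above the young means, and 1 aged mouse reaches the young range of Havcr2, Ifng and Ccl3.

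In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 824 of 9062 genes were higher and 623 lower in aged mice, of which 173 and 123 changed over 2-fold. Of the 1447 genes called, 1030 had a level in CD8 T-like cells at least as high as in other cells of the tumours. In mm10, Eomes (ENSMUSG00000032446) lies on chromosome 9 at 118478212 to 118486132, Gzmk (ENSMUSG00000042385) on chromosome 13 at 113171608 to 113225908, and Tox (ENSMUSG00000041272) on chromosome 4 at 6686353 to 6991557. Kcnj8 (ENSMUSG00000030247) spans 142564837 to 142571614 on chromosome 6, Fcgrt (ENSMUSG00000003420) 45092990 to 45103851 on chromosome 7, and Ifng (ENSMUSG00000055170) 118441046 to 118445892 on chromosome 10. Ccl3 (ENSMUSG00000000982) and Ccl4 (ENSMUSG00000018930) are neighbours on chromosome 11, at 83647844 to 83649355 and 83662584 to 83664683. The 3' libraries count transcript ends of these genes. Values of related family members such as Klra7 and its Klra relatives, Ccl3 and Ccl4, or the granzymes Gzmd to Gzmf are uncertain where reads match more than 1 of them.

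The numbers of genes called depended on the unit of replication and on single libraries. Counts summed per library called 493 genes higher and 325 lower, and kept 647 of the 1447 calls. Drawing 164 cells from every mouse called 207 and 184. Leaving out young replicate 1 called 337 and 195, young replicate 2 543 and 343, and aged replicate 1 501 higher. Of 34 named genes called, 13 kept their call without each library in turn, among them Eomes, Fcgr2b, Fcgrt, G0s2, Gzmk, Gzmm, Kcnj8, Maf, Pde2a, Tmem37, Treml2 and, of those that fell, Zbtb32. Without aged replicate 1, 17 calls were lost, those of Ccl3, Ccl4, Ccl5, Ifng, Havcr2, Tnfrsf9, Prf1, Pdcd1, Irf4, Egr3, Tcf7, Slamf6, Cxcr6, Slc17a6, Rgs16, Tg and Bdh2. Without young replicate 1, 15 were lost, those of Gzmb, Tox, Il7r, Klra7, Ccl3, Ccl4, Ccl5, Cxcr6, Havcr2, Ifng, Pdcd1, Prf1, Rgs16, Tg and Tnfrsf9. Without young replicate 2, 8 were lost, those of Bdh2, Cxcr6, Klra7, Pdcd1, Slamf6, Slc17a6, Tcf7 and Tnfrsf9, and without aged replicate 2, 3 were lost, those of Gzmb, Klra7 and Slamf6. With library as a random block, in which mice of a library count as correlated, the calls of Slamf6, Bdh2, Klra7 and Ccl5 were lost. Library sums lost the calls of Ccl5, Cxcr6, Il7r, Pdcd1 and Prf1, and equal cell numbers those of Ccl5, Pdcd1, Prf1, Slamf6, Tcf7 and Tg. Over all assigned cells of any type, 9 genes were higher and 1 lower. Among cells of any cluster with both Cd3 and Cd8 UMIs, 475 of the 1444 calls tested were kept and 180 had the opposite sign. There the calls of Fcgr2b, Tmem37, Tox, Tcf7, Il7r, Ccl5 and Klra7 were lost, and Fcgr2b turned to -0.10.

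Over all CD8 T-like cells together, most measured genes of naive and stem-like memory T cells rose in aged mice. About as many genes of inhibitory receptors fell. Some genes of costimulation, cytokines and killing fell as well, while most did not pass. Of 16 measured naive and stem-like memory genes, 10 rose, 3 fell and 3 did not pass (10 and 4 adjusted over the list alone), with S1pr1 at 1.6 and the quiescence factors Klf2 at 1.71, Klf3 at 1.29 and Satb1 at 0.92 on the log2 scale. Slamf6 (-0.51) and Ccr7 were among the 3 that fell. The list's adjusted p was 0.00554 in limma's camera test with a preset correlation, and adjusted p = 0.313 with an estimated correlation. Within cluster 2 the list went the other way, with 7 of 12 measured genes lower and none higher (camera adjusted p = 3.23e-08, and 0.0478 with an estimated correlation). Within cluster 1, 3 of 9 measured genes of the list were higher and none lower (camera adjusted p = 0.554). Of 17 inhibitory receptors and exhaustion regulators, 1 rose (Tox), 9 fell and 7 did not pass (1 and 10 adjusted over the list alone), with Ctla4 at -1.44, Nr4a2 at -1.31 and Nr4a3 at -1.69. For inhibitory receptors, camera gave an adjusted p of 3.87e-05, and adjusted p = 0.24 with an estimated correlation. Within cluster 1, 1 of the 8 measured genes of this list was called, lower in aged mice (camera adjusted p = 0.965). Among 11 costimulatory receptors, 5 fell and 6 did not pass (1 higher and 8 lower adjusted over the list alone), with Icos at -1.43, Tnfrsf9 at -1.38, Cd226 at -0.88 and Tnfrsf1b at -0.55. For costimulatory receptors, camera gave an adjusted p of 0.000137, and adjusted p = 0.24 with an estimated correlation. Among 14 cytokine and chemokine genes, 5 fell, 2 rose and 7 did not pass (7 and 2 adjusted over the list alone), including Lta at -0.97 and, in the other direction, Tnfsf8 at 1.34. For cytokines and chemokines, camera gave an adjusted p of 0.00234, and adjusted p = 0.313 with an estimated correlation. The 17 cytotoxic granule genes divided: Gzmk and Gzmm rose, 5 fell, among them Srgn at -0.60 and Serpinb6b at -0.96, and 10 did not pass (4 higher and 8 lower adjusted over the list alone). For cytotoxic granule genes, camera gave an adjusted p of 0.00918 for a decrease, and adjusted p = 0.326 with an estimated correlation. The call was also lost without aged replicate 1 (adjusted p = 0.178). Of 11 NK receptor genes, Klra3 (1.87) and Klra7 (2.45) rose, 3 fell, with Klrc1 at -0.92 and Klrd1 at -1.23, and 6 did not pass (2 and 6 adjusted over the list alone). For NK receptors, camera gave an adjusted p of 0.0459 for a decrease, and adjusted p = 0.313 with an estimated correlation. It did not pass with the replicate block (adjusted p = 0.0514) or without aged replicate 1 (0.303).

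Across all CD8 T-like cells, most measured glycolysis genes fell, as did a minority of the genes of oxidative phosphorylation and of the cell cycle. A few interferon-response genes rose. Of 19 glycolysis genes, 12 fell and 7 did not pass (14 adjusted over the list alone), with Tpi1 at -0.84, Ldha (lactate dehydrogenase A) at -0.74, the lactate exporter Slc16a3 at -0.89 and Bnip3 at -0.96. For glycolysis, camera gave an adjusted p of 2.72e-08, and adjusted p = 0.24 with an estimated correlation. Of 53 nuclear genes of oxidative phosphorylation, 8 fell and 45 did not pass (11 adjusted over the list alone), with Ndufc2 at -0.44, Ndufs5 at -0.51, Atp5g3 at -0.29 and Atp5k at -0.63. For oxidative phosphorylation, camera gave an adjusted p of 6.05e-10, and adjusted p = 0.313 with an estimated correlation. Of 30 proliferation genes, 7 fell and 23 did not pass (17 adjusted over the list alone), with Cenpa at -1.0, Ccnb1 at -0.82, Pclaf at -0.68 and Mcm3 at -0.52. For proliferation, camera gave an adjusted p of 1.48e-08, and adjusted p = 0.313 with an estimated correlation. Among 30 type I interferon response genes, 4 rose and 26 did not pass (4 adjusted over the list alone), namely Oasl2 at 1.31, Usp18 at 0.81, Oas3 at 0.76 and Slfn8 at 0.71. For type I interferon, camera gave an adjusted p of 0.000137, and adjusted p = 0.503 with an estimated correlation. Of 31 genes of interferon gamma response and antigen presentation, 7 rose, 1 fell and 23 did not pass (10 and 1 adjusted over the list alone), with the class I genes H2-Q4 at 0.81 and H2-Q6 at 0.60, Socs1 at 0.87 and, lower, Irf8 at -1.63. For interferon gamma and antigen presentation, camera gave an adjusted p of 0.00203, and adjusted p = 0.503 with an estimated correlation. Without aged replicate 2, that list did not pass (adjusted p = 0.103). Within cluster 1, camera called neither glycolysis (adjusted p = 0.965) nor proliferation (adjusted p = 0.95), though it called oxidative phosphorylation lower. Within cluster 2, camera called glycolysis higher (adjusted p = 0.00931), and neither proliferation (0.784) nor oxidative phosphorylation (0.252) was called.

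**Figure D3:**
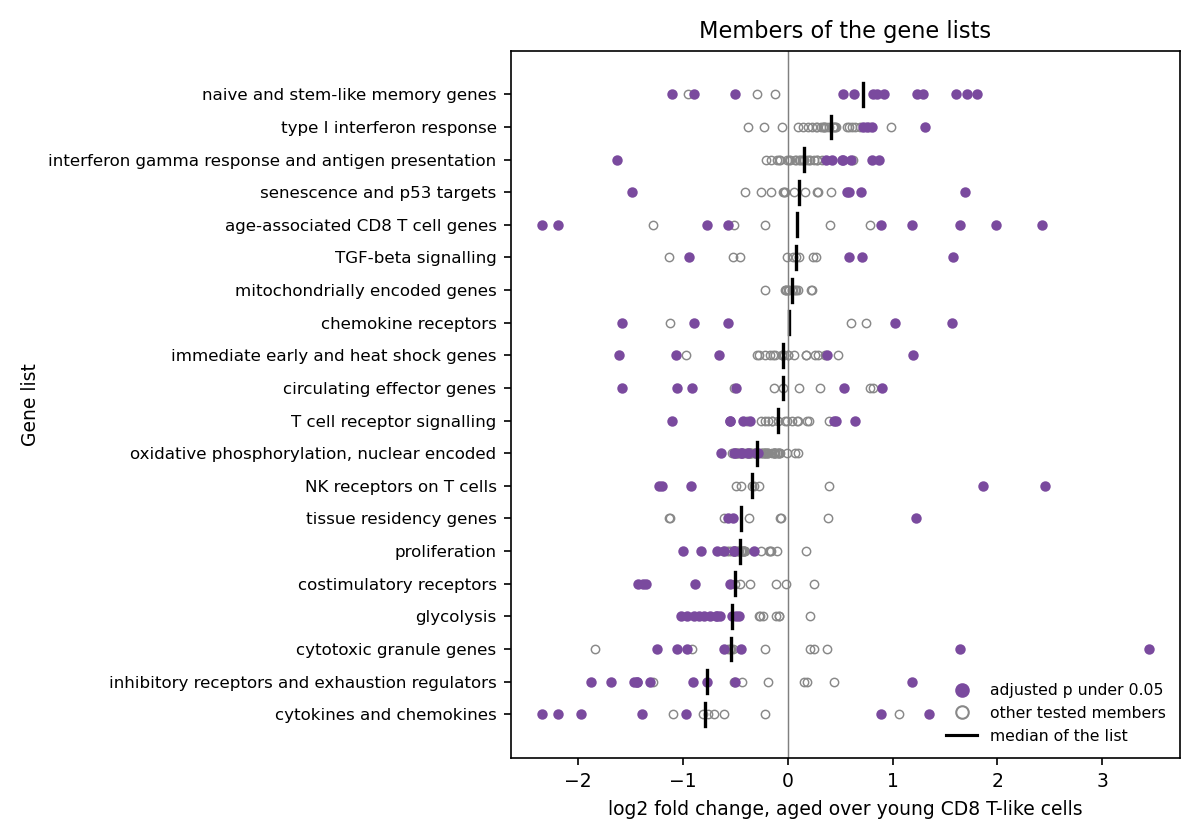
Log2 fold changes, aged over young CD8 T-like cells (horizontal axis), of the tested members of 20 gene lists fixed beforehand (vertical axis), with members at an adjusted p under 0.05 filled and list medians as black lines. Medians run from the naive and stem-like memory genes at 0.72 down to the cytokines and chemokines at -0.78.

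Lists of other cell types also moved within the CD8 T-like cells. All 3 measured gamma delta T cell transcripts rose, Tcrg-C4 by 4.93, Trdc by 3.84 and Tcrg-C2 by 3.01 (3 adjusted over the list alone). For gamma delta genes, camera gave an adjusted p of 0.0018, and adjusted p = 0.24 with an estimated correlation. Of 6 CD4 and regulatory T cell genes, 4 fell and 2 did not pass (5 adjusted over the list alone), with the interleukin-2 receptor chain Il2ra at -1.74, Ctla4 at -1.44, Tnfrsf4 at -1.35 and Ikzf4 at -1.12, all of which activated CD8 T cells can also express. For CD4 and regulatory T cells, camera gave an adjusted p of 2.94e-05, and adjusted p = 0.24 with an estimated correlation. Of 6 dendritic cell genes, the class II genes H2-Aa (-0.67) and H2-Ab1 (-0.60) fell and 4 did not pass (3 adjusted over the list alone), with H2-Eb1 at -0.45 and Batf3 at -1.39 among the latter. For dendritic cells, camera gave an adjusted p of 0.00234, and adjusted p = 0.24 with an estimated correlation. The macrophage and monocyte list was not called (1 higher, 1 lower and 10 of 12 not passing, 1 and 1 adjusted over the list alone; camera adjusted p = 0.999), although Lyz2 rose by 0.54 and Ctsb fell by 0.34, with Arg1 at 0.76 and Cst3 at -0.31. A Lyz2 UMI was present in 20.9% of aged and 16.7% of young CD8 T-like cells, a gene that T cells should lack. Of 3 B and plasma cell genes, Igkc rose by 2.49, while Cd79b (-0.06) and Ighm (-0.30) did not pass (1 adjusted over the list alone; camera adjusted p = 0.37). Of 8 NK cell genes, Eomes rose, Styk1 fell by 1.5 and 6, including Gzma and Klrk1 (-0.50), did not pass (1 and 4 adjusted over the list alone; camera adjusted p = 0.371). None of 6 tumour epithelium genes passed, such as S100a1 (-0.22), Prdx4 (-0.28), Mt1 (-0.33) and Mt2 (-0.22). Nor did any of 5 fibroblast and endothelium genes, such as Fabp4 (1.43), Sparc (-0.31), Pecam1 (0.17) and Col3a1 (-0.06). None of the 11 passed adjusted over the list alone either, and the camera adjusted p were 0.314 and 0.999.

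The remaining lists were not called by camera. Senescence and p53 targets had 4 higher and 1 lower of 16, with Bbc3 at 1.69, Zmat3 at 0.59, Cdkn1b at 0.56 and Gadd45b at -1.49 (5 and 1 adjusted over the list alone, adjusted p = 0.184). Tissue residency genes had 1 higher and 2 lower of 10, with Qpct at 1.22, Cxcr6 at -0.57 and Rgs1 at -0.52 (2 and 3 adjusted over the list alone, adjusted p = 0.231). Of 14 age-associated CD8 T cell genes, 5 rose, including Eomes, Gzmk, Tox and the survival gene Bcl2 at 1.99, and 4 fell (6 and 5 adjusted over the list alone; camera adjusted p = 0.689). T cell receptor signalling had 3 higher, including Fyn (0.44), Ubash3a (0.46) and Nfatc2 (0.65), and 5 lower of 23, including Ubash3b at -1.11 (4 and 6 adjusted over the list alone; adjusted p = 0.33). Circulating effector genes had 2 higher, including Ifngr1 (0.54), and 4 lower of 13, including Cx3cr1 at -1.58, Zeb2 at -1.06 and Id2 at -0.50 (4 and 5 adjusted over the list alone; adjusted p = 0.416). TGF-beta signalling had 3 higher (Smad3 at 1.57, Smad7 at 0.71, Nrros at 0.59) and 1 lower (Itgav at -0.94) of 13 (3 and 3 adjusted over the list alone; adjusted p = 0.585). Chemokine receptors had 2 higher, including Cxcr4 at 1.56, and 3 lower of 8, including Ccr7 at -0.89 (4 and 4 adjusted over the list alone; adjusted p = 0.689). Immediate early and heat shock genes had 2 higher (Ier3 at 1.19, Dnajb1 at 0.38) and 3 lower of 24, including Nr4a1 at -1.61 and Egr1 at -0.66 (2 and 3 adjusted over the list alone; adjusted p = 0.384). None of the 13 mitochondrially encoded genes passed (adjusted p = 0.689).

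In the tests of 28 lists, 4 rose and 10 fell with the preset correlation of 0.01, and none was called with estimated correlations, where the smallest adjusted p was 0.24. In fry, which asks whether a list's genes move on balance in 1 direction, 14 lists were called. They included senescence and p53 targets (adjusted p = 0.00957) and tissue residency genes (0.00474), which camera did not call, but not type I interferon response (adjusted p = 0.0975) or interferon gamma response and antigen presentation (0.0697). In limma's values, median and mean differed in sign for the age-associated list (0.09 and -0.10), the B and plasma cell list (-0.05 and 0.73), the macrophage list (-0.03 and 0.05) and the fibroblast and endothelium list (-0.05 and 0.10, test downward). For chemokine receptors, edgeR's median was 0.01 while limma's was -0.03 and its test pointed downward.

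Within the interferon-stimulated-like cluster 1, aged cells again expressed more Eomes, at 118 ± 52.9 CPM (SD, n = 7) against 15.7 ± 9.57 CPM (SD, n = 7) in young mice (log2 fold change 2.77, SE 0.31, edgeR adjusted p = 2.64e-06). Ms4a4c (1.88), Tspan3 (1.5), the NK receptor gene Klre1 (1.38) and Il7r (1.21) also rose, although Tspan3 was higher still in other cells of the tumours. Plac8 fell from 2047 ± 740 CPM (SD, n = 7) in young to 557 ± 192 CPM (SD, n = 7) in aged mice (log2 fold change -1.90, SE 0.22, edgeR adjusted p = 4.42e-06), and Car2 (carbonic anhydrase 2, -2.07), Slamf1 (-1.60), Fam241a (-1.52) and Fhl2 (-1.03) were also lower. In all, 46 of 3495 genes were higher and 29 lower. Counts summed per library called 30 and 10, but kept only 16 of the 75 calls. Leaving out a library called 12 to 90 higher and 8 to 130 lower, fewest without young replicate 2. The calls of Ms4a4c, Klre1, Il7r and Fam241a were lost without young replicate 2, Car2 without aged replicate 1, Slamf1 without aged replicate 2, and Fhl2 without either aged replicate, with DESeq2 and with library sums. Splitting the same mice across ages, aged replicate 1 with young replicate 2 against the others, called 120 genes, more than the 75 called between ages. Of 22 lists, type I interferon response (adjusted p = 1.31e-07), interferon gamma response and antigen presentation (0.000304) and NK cell genes (0.00327) were called higher by camera and oxidative phosphorylation lower (1.31e-07), and none held with an estimated correlation (adjusted p = 0.501, 0.538, 0.106 and 0.501).

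Within the naive or central memory-like cluster 2, aged cells carried more transcripts of killing genes and fewer of the naive and stem-like program. Gzmm averaged 218 ± 151 CPM (SD, n = 7) in aged and 45.8 ± 29.2 CPM (SD, n = 7) in young mice (log2 fold change 2.49, SE 0.41, edgeR adjusted p = 0.000385), and Gzmb averaged 391 ± 277 CPM (SD, n = 7) and 144 ± 76.8 CPM (SD, n = 7; log2 fold change 1.43, SE 0.36, edgeR adjusted p = 0.0136). Gzmb thus rose within this cluster while it fell over all CD8 T-like cells. Fcgrt (3.12), Lpin1 (1.52) and the calcium-binding S100a6 (1.40, higher still in other cells of the tumours) rose too. Dapl1, a marker of naive CD8 T cells, averaged 29.9 ± 28.0 CPM (SD, n = 7) and 179 ± 51.0 CPM (SD, n = 7; log2 fold change -3.45, SE 0.38, edgeR adjusted p = 2.49e-06), and Slamf6 (-2.43), the lymph node homing receptor Ccr7 (-1.45), Itga4 (-1.31) and Zfp36 (-1.22) fell as well. Of 12 naive and stem-like memory genes measured, 7 fell and none rose (camera adjusted p = 3.23e-08, adjusted p = 0.0478 with an estimated correlation). Of 11 cytotoxic granule genes 6 rose (camera adjusted p = 7.14e-06; adjusted p = 0.0735 with an estimated correlation). Camera also called interferon gamma response and antigen presentation (adjusted p = 0.000758), glycolysis (0.00931), NK cell genes (0.0111) and age-associated genes (0.0256) higher, and mitochondrially encoded (7.14e-06) and immediate early and heat shock genes (0.00266) lower, of 21 lists. None of these 6 held with an estimated correlation, where their smallest adjusted p was 0.131. In all, 105 of 2298 genes were higher and 70 lower. Counts summed per library called 61 and 43, but kept only 32 of the 175 calls. Leaving out young replicate 2 called 25 and 25, which ended the calls of Gzmm, Gzmb and Itga4. Leaving out aged replicate 1 called 220 and 275.

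The age difference itself differed between clusters 1 and 2 for 28 of 2845 genes, 14 in each direction, in limma's test on the difference between the clusters within each mouse (Benjamini-Hochberg adjusted, 7 aged and 7 young mice). By smallest p, the genes were S100a6, whose age difference was lower by 1.40 (log2 units, -1.40) in cluster 1 than in cluster 2 (adjusted p = 0.00348), Plac8 (-2.11, adjusted p = 0.00601) and the transcription factor gene Ikzf2 (2.66, adjusted p = 0.00656), named after their values were seen. The comparison planned between clusters 0 and 1 could not be fitted, because only 2 aged mice had enough cells in cluster 0, and clusters 1 and 2 were chosen in their place. Leaving out any 1 library left at most 4 genes in either direction, with 445 genes at an unadjusted p under 0.05 in the full comparison.

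The diversity of T cell receptor beta variable genes (Trbv) was compared in the mice with at least 25 Trbv UMIs, 3 aged and 7 young. Shannon evenness over 20 Trbv genes, thinned to 29 UMIs per mouse, was 0.577 ± 0.115 (SD, n = 3) in aged and 0.696 ± 0.067 (SD, n = 7) in young mice and did not pass a two-sided exact permutation test (p = 0.075). The Simpson index averaged 0.752 and 0.842 (exact p = 0.0417). With 4 to 106 Trbv UMIs per mouse and 5 mice left out, the depth allows no firm statement on either side.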

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

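The comparisons of hashtag separation and of a swapped mouse were chosen after the result was seen, as were thinned and macrophage-like values of the receptor transcripts, and the Cd8b1 and cluster comparisons of those transcripts were fixed before. An outlier test marked 28 of 109 groups of mice, and 14 of the 28 were values of aged replicate 2 mouse 3. About 5.45 would be marked by chance if values were normally distributed and groups independent. The same mice entered many of the groups, so this number is only a rough guide.

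Aged replicate 2 mouse 3 lay far from the other aged mice in several values, with 36.0% of its CD8 T-like cells in cluster 0 (other aged mice 0.61% to 8.88%), and its granzyme cluster 7 held 10.9% (other aged mice 0% to 2.34%, young mice up to 5.54%). In CPM, it had Ccl3 at 1215, Ccl4 at 2957, Ifng at 1203, Rgs16 at 351, Slc17a6 at 36.2, Tg at 29.0, Bdh2 at 16.7, Pdcd1 at 572, Havcr2 at 144, Lag3 at 424, Prf1 at 546 and Cxcr6 at 772, each above all other aged mice. Unseparated hashtags might carry its cells into the other mice of its library, and their highest cluster 0 share was 0.94%, but low shares in them are part of the pattern itself, so this was left open. A young mouse in its place might look like this, but its granzyme K memory-like cluster 4 held 11.47%, against at most 1.28% in young mice, which argues against it unless cells of its library were mixed. No biological explanation was tested.

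Transcripts of any of the gamma delta T cell receptor constant genes Trdc, Tcrg-C1, Tcrg-C2 and Tcrg-C4 were found in 19.2% ± 13.2 (SD, n = 7) of CD8 T-like cells in aged and 3.36% ± 1.38 (SD, n = 8) in young mice (two-sided exact permutation test, p = 0.0002, the smallest possible). Thinned to 1000 UMIs per cell, the shares were 12.0% ± 9.77 (SD, n = 7) and 1.75% ± 0.836 (SD, n = 8; exact p = 0.0002), and in macrophage-like cells thinned alike they were 0.199% ± 0.178 (SD, n = 7) and 0% (n = 8; exact p = 0.007). Gamma delta T cells among the cells kept might explain this, but Cd8b1, a chain of conventional CD8 T cells, was detected 1.05 times as often in positive as in other aged cells of like depth (80.6% and 76.8%). That ratio pools 634 positive cells over aged mice, and aged replicate 1 mouse 3, with 45.8% of its 717 cells positive, carries much of it. In cluster 2, however, Cd8b1 was found in 68.6% of positive and 80.0% of other aged cells and in 30% and 69.5% of young cells, so gamma delta cells there are not excluded at either age. Free RNA might also contribute, but the share of positive aged cells differed 5.48-fold among clusters 1, 2 and 4 (24.9%, 7.79% and 42.7%). These shares pool aged mice, whose own shares ran from 6.95% to 45.75%. The highest, aged replicate 1 mouse 3, also held 44.9% of its cells in cluster 4, so the fold does not separate clusters from mice. Near-identical Tcrg-C copies leave their separate counts uncertain.

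The other values marked as far from their group were single mice. Among aged mice, Gzmm reached 326 CPM, Treml2 67.7 and Klra7 119 in replicate 2 mouse 2, and Gzmk 463 in replicate 2 mouse 1. Itgae reached 45.3 CPM in replicate 1 mouse 1, cluster 3 held 12.2% in replicate 1 mouse 2, and replicate 1 mouse 3 had Tox at 250 CPM and the receptor transcripts in 45.8% of cells. Among young mice, cluster 5 held 21.1% in replicate 1 mouse 1. Replicate 1 mouse 2 had Maf at 13.9 CPM, Rgs16 at 575, Entpd1 at 43.5 and Prf1 at 1127, and replicate 2 mouse 4 had Klrg1 at 16.9 CPM.

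The age difference differed between clusters 1 and 2 for 28 genes, which marked it as a difference between groups. None of the other 99 splits of the mice gave as many, and their highest number was 0, so only 1 of 100 splits, the real one, reached 28. The clusters were chosen after the data were seen, and with a library left out at most 4 genes remained in either direction.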

How the results depend on the processing

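Of 1756 comparisons of single named genes with alternatives, 1525 kept direction and side of the threshold, 192 fell short of it, 34 newly passed it and 5 reversed. Of 224 for lists, 180 kept both, 23 fell short, 8 newly passed and 13 reversed, and of 107 for shares the numbers were 87, 11, 2 and 7. Library and age cannot be separated, depth limits genes of low counts, and the cause was not tested for any change below unless stated.

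Over all CD8 T-like cells, leaving out a library gave 337 to 735 genes higher and 195 to 679 lower, and leaving out a mouse gave 564 to 1024 and 380 to 939. Library sums gave 493 higher and 325 lower, those with cells of no hashtag 505 and 346, and all assigned cells 9 and 1. Equal cell numbers gave 207 and 184 (fewer cells). The Cd3 and Cd8 gate gave 654 and 733, within 1.5 times of the numbers reported, but these were largely other genes. It kept 475 of the 1444 calls tested, and 180 had the opposite sign. Among genes at or above their level in other cells, 713 were higher and 384 lower (fewer genes tested), and only the number lower moved by over 1.5 times.
In cluster 1, no filter gave 117 higher and 109 lower, library sums 30 and 10, crossed replicate numbers 72 and 58, and leaving out a library 12 to 90 and 8 to 130. In cluster 2, these gave 273 and 130, 61 and 43, 151 and 168, and 25 to 220 and 25 to 275. The difference between clusters had 0 to 1 genes higher and 0 to 4 lower without a library.
In macrophage-like cells, DESeq2 gave 47 higher and 53 lower, DESeq2's size factors 5 higher, no filter 13 higher, library sums 0 and 0, crossed numbers 33 and 52, and leaving out a library 0 to 129 and 0 to 268. In large cells, DESeq2 gave 43 and 37, no filter 2 lower, library sums 0 and 0, the replicate block 20 and 15, crossed numbers 69 and 208, and leaving out a library 0 to 393 and 0 to 732.

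Over all CD8 T-like cells, no list was called with an estimated correlation (0 higher, 0 lower). Replicate numbers are only shared, not paired (correlation of deviations -0.124); blocking on them called 1525 genes and crossed numbers 871 higher and 774 lower.

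Shares, aged minus young in points, fell short with library means for clusters 0 (-36.1), 2 (28.3), 3 (-5.15), 4 (24.6) and 5 (-5.91), which have 2 values per age, and for cluster 3 clustered without age-dependent genes (-2.65). Without aged replicate 1, clusters 0 (-32.3) and 5 (-6.14) fell short, without aged replicate 2 clusters 3 (-4.32) and 5 (-5.69), and without young replicate 1 cluster 3 (-3.23), while cluster 1 newly passed (-12.5). Over the 4 libraries left out, the extremes were -40.9 for cluster 0, -6.84 for cluster 3, -8.46 and -3.29 for cluster 5, -1.80 for cluster 7 and 0.392 for cluster 9. Cluster 7 newly passed without aged replicate 2 mouse 3 (-1.98). Cluster 1 reversed at resolution 0.3 (13.1), with young-only clusters (27.8), without age-dependent genes (0.911) and without young replicate 2 (1.70), cluster 9 with young-only clusters (-0.193) and without aged replicate 1 (-0.0314), and cluster 7 without aged replicate 1 (1.27). Cluster 4 had no counterpart at resolution 0.3, with young-only clusters or without age-dependent genes, so its cells carried other labels there.

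Entpd1 reversed over all assigned cells (-0.021) and the gate (-0.32), Klrg1 in the same settings (-0.45 and -0.55) and Fcgr2b in the gate (-0.10). The fibroblast and endothelium list reversed with fry (adjusted p = 0.967), the random block (0.992) and without aged replicate 2 (0.365) or young replicate 1 (0.557), with 0.216 as its lowest value without a library. Immediate early genes reversed without aged replicate 1 (0.259) or young replicate 1 (0.93), with values from 0.050 without a library. Mitochondrially encoded genes reversed without aged replicate 1 (0.00137) or young replicate 1 (0.33), with values from 0.000285. Macrophages reversed without aged replicate 1 (0.259) or young replicate 2 (0.922). Age-associated genes (0.877) and tumour epithelium (0.498) reversed without aged replicate 2, with lowest values without a library of 0.47 and 0.0393. Circulating effector genes reversed without young replicate 2 (0.965), with a lowest value of 0.111. Trbv evenness passed as Simpson index (-0.0900), with a block (-0.119) and without aged replicate 2 (-0.185), and was 0.0127 without aged replicate 1, a change of sign that rests on 1 aged mouse, mouse 3 of aged replicate 2.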

Other observations

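The test of library preparation in other cell types and that of cluster shares were written after the result was seen, and the tests of other cells' RNA and of other splits of the mice were fixed before.

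The cells assigned to a mouse differed in type between ages. T cells of the first clustering led by Gzmf, Ccl3, Ifng and Pdcd1 made up 2.06% ± 2.17 (SD, n = 7) of assigned cells in aged and 21.2% ± 7.5 (SD, n = 8) in young mice (two-sided exact permutation test, Benjamini-Hochberg adjusted p = 0.005). Cells led by the epithelial keratins Krt19 and Krt8 made up 1.39% ± 1.38 (SD, n = 7) and 0.158% ± 0.3 (SD, n = 8; exact adjusted p = 0.0066), a difference of 1.23 points that was 0.633 without aged replicate 2 (exact adjusted p = 0.0323). Cells mixing class II genes with T cell transcripts made up 5.07% ± 2.63 (SD, n = 7) and 10.8% ± 2.70 (SD, n = 8; exact adjusted p = 0.0066), and the Acp5 and Mmp9 cells 20.0% ± 21.5 (SD, n = 7) and 2.98% ± 0.635 (SD, n = 8; exact adjusted p = 0.0081), which did not hold without aged replicate 2 (0.129). Macrophage-like cells were 5.86 points higher in aged mice (exact adjusted p = 0.349), and 14.8 points higher without aged replicate 2 (0.0323). T cells led by Bcl2 and Gzmm were 5.96 points higher (exact adjusted p = 0.0634), and 8.09 points higher without that library (0.0323).

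In macrophage-like cells, Gdf3, a TGF-beta family ligand, averaged 70.7 ± 15.7 CPM (SD, n = 7) in aged and 36.2 ± 6.18 CPM (SD, n = 8) in young mice (log2 fold change 0.98, edgeR adjusted p = 0.00352). Ccl4 averaged 133 ± 45.8 CPM (SD, n = 7) and 319 ± 63.4 CPM (SD, n = 8; log2 fold change -1.27, edgeR adjusted p = 0.0138). In all, 8 of 9582 genes were higher and 4 lower there, and in large cells 2 of 12133 were higher, Hmox1 by 0.57 and Pf4 by 1.56, both at a higher level in other cells of the tumours (149.7 and 196.8 CPM in aged mice) than in the large cells. All of these calls, in both cell types, were lost without young replicate 1 and with counts summed per library. Of 40 splits of the mice, 3 gave as many genes in macrophage-like cells and 3 in large cells, with up to 203 and 730 genes, so neither number stands apart from differences between libraries.

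The 1447 genes called between ages over all CD8 T-like cells were weighed against technical sources. Of 100 splits of the mice, 1 gave as many genes, the real one, and the highest other number was 325, although the real split is also a split of libraries. Free RNA of other cells could raise or lower such genes, but 0.28% of them lay within the bound set by the background. Library preparation that acted on every cell type could too, but their median shift in macrophage-like and large cells was at most 6.56% of that in CD8 T-like cells. The genes were chosen for their difference in CD8 T-like cells, and an effect of preparation on T cells alone would not show in other cells, so it stays open. Changed cluster shares alone could also move them, and the 250 genes called within clusters 1 and 2 leave this open, since in cluster 1, where 2 of 100 splits gave as many, the split of aged replicate 1 and young replicate 2 against the others called 120 genes, more than the 75 of the real one. In cluster 2, 1 of 100 splits, the real one, reached its 175 genes, and the highest other number was 133.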
